A study of Homo sapiens with 4 samples.

How the data were processed

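RNA from MIA PaCa-2 cells was measured on Illumina WG-6 v3 bead chips, with 1 array per sample: 2 untreated controls and 2 samples given IL-1β at 2 ng/ml for 36 h, per the labels. The raw file holds probe intensities on a linear scale with no background subtraction, as deposited by the authors, and a detection p-value per probe and array, per the file headers. The software that read the arrays is not given in the sources used here. In the deposited series matrix the authors had subtracted 1 constant per array from the intensities and then applied 1 factor per array, so that all arrays have a mean of 322. In the authors' deposited table of averages the intensities of each array had been multiplied by 1 factor, between 0.914 and 1.12, and averaged per group, with no background subtraction. These steps were read from the values, since each column is a fixed function of the raw column. The authors' deposited score table has no header and holds a signed score per gene; its formula is not given in the sources used here, and the smallest size of a score is 13. The descriptions in that table slip out of line with its symbols and were not used.

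The raw intensities were background corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, which infers the background from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. Probes with a detection p under 0.01 on at least 2 arrays were tested, 13152 of 48803. Groups were compared with lmFit and eBayes of limma, two-sided, with p adjusted by Benjamini and Hochberg over all probes tested and a threshold of 0.05. A second count, with no test, took probes at least 1.5-fold apart whose groups do not overlap. The median SE of a log2 difference was 0.111, with 5.52 degrees of freedom including those of the prior. Where the text gives a range after a fold, it is the 95% confidence interval. Gene names came from the table that pairs the array's probes with genes: 27578 probes have 1 gene, 13 have several and were left unnamed, and 21212 are not listed there. The probes tested cover 8862 named genes, each read by its tested probe with the highest mean. Of 2004 genes with more than 1 tested probe, 9 had probes past an unadjusted p of 0.05 in opposite directions.

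Lists of genes, 26 in all, were fixed before the data were examined, as were the tests, the thresholds and most of the alternatives. They cover NF-κB, chemokines and cytokines, acute-phase and innate defence, IL-1 receptor signalling, interferon-stimulated genes, AP-1, EGFR and MAPK feedback, Wnt, TGF-β, the cell cycle, p53, apoptosis, epithelial and mesenchymal markers, matrix remodelling, hypoxia, the unfolded protein response, cholesterol biosynthesis, oxidative phosphorylation, oxidative stress, the proteasome, antigen presentation, ribosomal proteins, histones and 3 sets of markers of other cell types. Each list with at least 3 tested genes was compared with all other genes by camera of limma with its preset correlation of 0.01, adjusted over 25 lists, and again with the correlation estimated from the data. Each list was also tested by itself against no change with fry of limma. Members were also adjusted over the list alone.

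The rule for named genes was fixed before the data were examined. It takes the largest differences past the threshold, filled up to 5 per direction where fewer pass, and the leading member of each list. It also takes 8 genes fixed by name, which are the receptor gene IL1R1 and genes known to respond to IL-1. Last, it takes the 3 genes with the largest scores in each direction of the authors' table. Ties at the largest score were ordered by the ratio of the authors' means. Further list members given as examples, and the genes that open the observations, were chosen after their values were seen. The alternatives changed the background correction, the scaling, the filter, the averaging of probes, the variance model and the thresholds, used a replicate block, or left out each array in turn. The authors' series matrix values were floored at 16 before log2.

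The fit was tested on simulated data with the probe means and variance prior of these arrays, in 20 simulations of 13152 probes. In each, 200 probes were changed, in a mix of the sizes below, and the tested cell-cycle genes were shifted by 0.3 in the same data. The fit called 2.17% of probes changed 1.41-fold, 71.7% of those changed 2-fold and 97.9% of those changed 4-fold, and 0.0399% of unchanged probes. These shares depend on that mix, so they do not give the share of real changes found here. The shifted cell-cycle list was called in 20 of 20 simulations, and other lists in 1 of 480 tests. The simulated probes varied independently, so these list counts do not cover lists whose genes are correlated.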

Results

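Gene expression was measured in MIA PaCa-2 cells, an established human cell line derived from a pancreatic carcinoma, after 36 h with 2 ng/ml IL-1β and in untreated cells. IL-1β is an inflammatory cytokine that acts through the IL-1 receptor and is known to activate NF-κB. Each group held 2 samples, and each sample was hybridised to 1 bead chip array of 48803 probes. The labels do not state that the samples of a group came from separate cultures, so the p-values of single probes measure the spread between these samples, which may be technical. The camera p-values with the preset correlation rest on the spread between genes taken as nearly independent. They do not measure how well a list shift repeats between samples. With an estimated correlation no list passed, and the smallest adjusted p in camera was 0.388. That form has few degrees of freedom with 2 arrays per group, so not passing it does not count against a list. Between 12740 and 13157 probes were detected per array, or 26.1% to 27.0% of all probes. The mean raw intensity was 527 and 549 on the control arrays and 482 and 449 on the IL-1β arrays. Over the 13152 probes tested, the SD of the log2 difference between arrays was 0.22 within the control group, 0.23 within the IL-1β group and 0.29 to 0.30 between arrays of different groups. The number of arrays limits the precision of every value.

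The comparison of IL-1β-treated with untreated cells asks which transcripts differ between the groups. The genes with the largest higher values after IL-1β included several of immune function. C1S, a serine protease of the first complement component, was 2.76-fold higher (95% confidence interval 2.22 to 3.44), with log2 intensities of 8.85 ± 0.03 with IL-1β and 7.39 ± 0.20 in controls (mean ± SD, 2 arrays each). EBI3, a subunit of the cytokines IL-27 and IL-35, was 2.46-fold higher (2.04 to 2.97), and LAMP3, a lysosomal membrane protein known from mature dendritic cells, was 2.4-fold higher (1.97 to 2.94). CCL22, a chemokine that binds CCR4, was 2.17-fold higher (1.84 to 2.55), and CFB, complement factor B, was 2.15-fold higher (1.8 to 2.57). CLGN, a chaperone of the endoplasmic reticulum, was 2.45-fold higher (1.76 to 3.39), with its probe detected on 1 of the 2 control arrays.

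Among the lower genes, ANGPTL4, a secreted inhibitor of lipoprotein lipase, was 2.28-fold lower after IL-1β (1.72 to 3.01), with log2 intensities of 6.55 ± 0.31 against 7.74 ± 0.04 in controls. PRSS23, a serine protease, was 2.17-fold lower (1.83 to 2.57), and ITGA10, an integrin subunit that binds collagen, was 2.16-fold lower (1.63 to 2.85). CCDC190, a coiled-coil protein, was 2.28-fold lower (1.79 to 2.91) and EPHX4, named as an epoxide hydrolase, was 2.24-fold lower (1.6 to 3.14). DKK1, a secreted antagonist of Wnt signalling, was 1.79-fold lower (1.5 to 2.15). MALL, a membrane protein of the MAL family, was 1.68-fold lower (1.42 to 1.98), and GPAT3, an acyltransferase of triglyceride synthesis, was 1.65-fold lower (1.39 to 1.96). In each of these genes both IL-1β arrays lay on the same side of both control arrays.

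**Figure D1:**
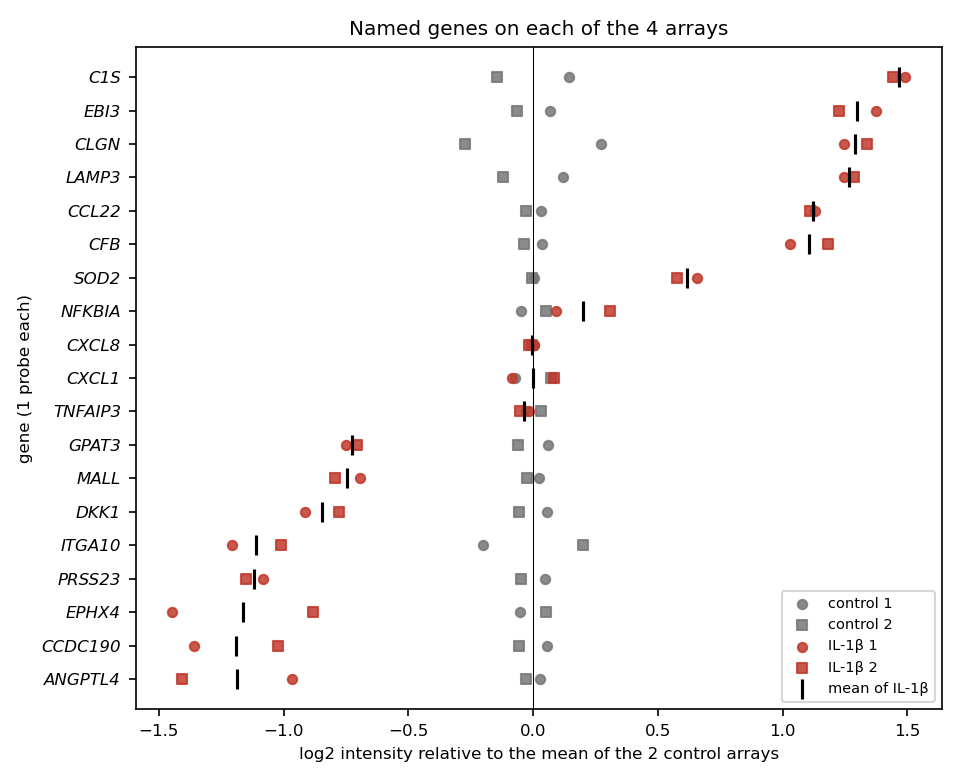
Log2 intensity of 19 named genes on each of the 4 arrays, relative to the mean of the 2 control arrays (horizontal axis); circles and squares are the arrays numbered 1 and 2 of each group, and the bar is the mean of the IL-1β arrays. C1S lies at 1.47 and ANGPTL4 at -1.19, while CXCL8 and CXCL1 have their IL-1β and control arrays together near 0.

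None of these genes passed an adjusted p of 0.05 in limma. The adjusted p was 0.0774 for C1S, EBI3, LAMP3, CCL22, CFB, CCDC190 and PRSS23, lay between 0.0786 and 0.092 for DKK1, MALL, ANGPTL4, GPAT3, CLGN and ITGA10, and was 0.104 for EPHX4. Of 13152 probes tested, 0 passed in limma with its default variance model, 124 had an adjusted p under 0.1 (67 higher, 57 lower) and 2437 had an unadjusted p under 0.05 (1217 higher, 1220 lower). The count past an adjusted p of 0.05 was 254 with an offset of 50 in the background correction, 624 with no background correction and 728 with limma's trend and robust settings. It was 919 with median scaling (58 higher, 861 lower) and 1097 with the authors' averaged-table scaling (239 higher, 858 lower), where the split is uneven. Under all 3 of the former settings 247 probes were called, 125 higher and 122 lower, which include probes of 201 named genes and others without a gene name. By size, 401 probes were at least 1.5-fold apart with no overlap between the groups (200 higher, 201 lower), and 32 were at least 2-fold apart (15 higher, 17 lower). The groups did not overlap in 50.7% of the tested probes, where chance gives 33.3%.

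The split between higher and lower probes moved with the scaling. Among probes with an unadjusted p under 0.05, 50.1% were lower after the quantile normalization used here, 74.4% in the authors' series matrix values and 72% with the factors of the authors' averaged table. Median scaling over all probes gave 94.3% lower, and it moved the median of the tested probes by -0.22 on the log2 scale, while the other scalings moved it by less than 0.1. Values given below for median scaling, unless over tested probes, carry this shift. Over all tested probes 50.3% were lower with quantile normalization, 64.3% in the authors' series matrix values and 47.2% with median scaling over tested probes. DKK1, C1S, CCL22, CFB and SOD2 kept their direction under every scaling and background setting tried, with log2 differences from -1.10 to -0.72 for DKK1 and from 0.92 to 1.48 for C1S. The range was wider for PRSS23 (-1.40 to -0.44), ANGPTL4 (-1.44 to -0.58), EPHX4 (-1.41 to -0.58) and CLGN (0.58 to 1.40). The folds of these dimmer genes thus depend more on the processing.

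**Figure D2:**
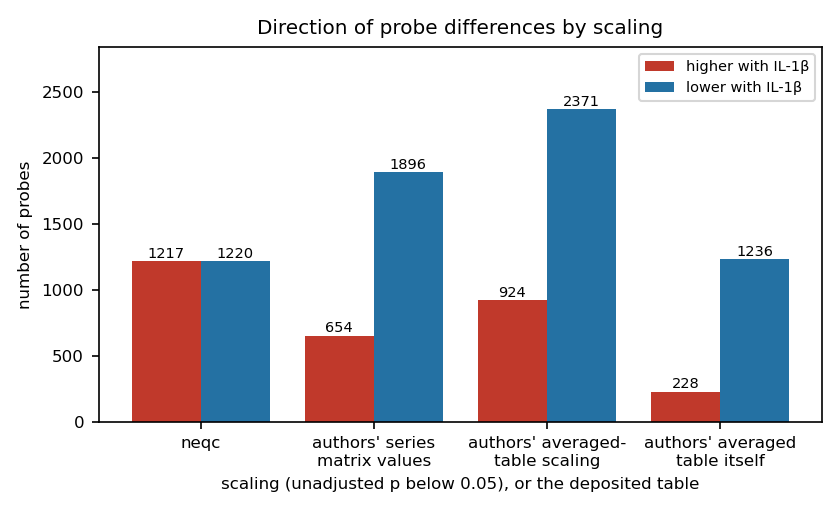
Number of probes (vertical axis) higher (red) and lower (blue) after IL-1β: for the first 3 pairs of bars, probes with an unadjusted p under 0.05 under each scaling, and for the last pair, all probes of the authors' averaged table. With quantile normalization 1217 were higher and 1220 lower, and the authors' averaged table held 228 higher and 1236 lower.

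Genes of acute-phase and innate defence were higher as a group. Of 9 members tested, 8 were higher, with a median log2 difference of 0.37, and 5 rose adjusted over the list alone. These were C1S, CFB, LCN2, C1R and CEBPD, which encode complement proteases and factor B, an iron-sequestering protein of the acute phase and a transcription factor of inflammation. LCN2 rose by 0.82 ± 0.10 and C1R by 0.81 ± 0.09 on the log2 scale (± SE, as in the text that follows), and CEBPD rose by 0.37 ± 0.11. The other probe of C1R, which is dimmer, was at 1.41. C3, the central complement component, differed by -0.17 ± 0.20, was detected on 1 of the 2 IL-1β arrays and changed sign under the authors' averaged-table scaling. The shift of the list against all other genes had adjusted p = 0.000224 in camera, and adjusted p = 0.388 with an estimated correlation. Tested against no change, the list had adjusted p = 0.0368 in fry. With no filter on dim probes the median over 23 members was 0.077 (adjusted p = 0.0112 in camera), and 4 rose over the list alone. The median was 0.196 with median scaling, and without IL-1β replicate 1, 4 rose and 1 fell over the list alone.

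Some chemokines and cytokines rose, and others were at the control level or did not pass. Of 16 tested, 12 were higher, with a median of 0.39, and 8 rose adjusted over the list alone: IL32, CX3CL1, CSF3, TNFSF15, TNF, VEGFA, CXCL16 and CXCL6. CSF3, the granulocyte colony-stimulating factor, rose 1.58-fold (1.34 to 1.86), IL32 rose by 0.84 ± 0.15 and CX3CL1, a membrane-bound chemokine, by 0.67 ± 0.10. The other probes of CSF3 and IL32 were at 0.26 and 0.52. TNF rose by 0.47 ± 0.11, and the probe of CXCL6 was not detected on either control array. Some neutrophil-attracting chemokines known as targets of IL-1 were at the control level: CXCL8 was 0.998-fold (0.852 to 1.17), CXCL1 was 1.00-fold (0.822 to 1.22), CXCL2 differed by -0.03 ± 0.09 and CXCL5 by 0.03 ± 0.09, with the signs of CXCL8 and CXCL5 turning between scalings. IL6 was not detected on any array. The list had adjusted p = 0.000692 in camera, adjusted p = 0.388 with an estimated correlation, and 0.0368 in fry. With no filter on dim probes the median over 31 members was 0.082 (adjusted p = 0.00631 in camera), and over the list alone 3 rose and 1 fell. With median scaling the median was 0.162, with 3 that rose and 1 that fell. With the authors' averaged-table scaling it was 0.237, with 8 and 1, and 3 rose in their series matrix values. Without control replicate 1, 2 of its members rose, and without each of the other arrays 4 to 7 did.

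Of 25 interferon-stimulated genes tested, 21 were higher, with a median of 0.22, and 3 rose adjusted over the list alone. IFI27 rose 1.86-fold (1.55 to 2.24), XAF1, an antagonist of apoptosis inhibitors, rose by 0.76 ± 0.10, and OAS2, an antiviral synthetase of oligoadenylates, by 0.56 ± 0.10. Probes disagreed in size, with the other probe of XAF1 at 0.04 and those of OAS2 at 0.57, 0.15 and 0.11. The other 22 did not pass, and 1 member passed with median scaling or with probes averaged per gene. Over the list alone 9 rose and 1 fell with no background correction, and 10 rose and 1 fell with trend and robust settings. The median was 0.143 without control replicate 2. The list had adjusted p = 0.000144 in camera, adjusted p = 0.443 with an estimated correlation, and 0.0846 in fry.

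Of 19 genes of antigen presentation, 16 were higher, with a median of 0.23. CD74, the invariant chain of MHC class II, rose 1.5-fold (1.26 to 1.79), HLA-B by 0.58 ± 0.11 and TAPBP, which loads peptides on MHC class I, by 0.41 ± 0.10, all adjusted over the list alone. The other probes of TAPBP were at -0.28 and 0.07, so its direction depends on the probe, and that of CD74 was at 0.31. TAP1, a peptide transporter, differed by -0.09 ± 0.09 and was among the 16 that did not pass. The list shares PSMB8, PSMB9 and PSMB10 with the proteasome list. It had adjusted p = 0.000228 in camera, adjusted p = 0.388 with an estimated correlation, and 0.0846 in fry. No member passed over the list alone when any 1 array was left out, with no filter, with median scaling or in the authors' series matrix values. The median was 0.353 without IL-1β replicate 2. Over the list alone 5 rose with an offset of 50 or with detection on all 4 arrays. With no background correction or with trend and robust settings 6 rose, and the median with no background correction was 0.122.

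Cell-cycle and proliferation genes were higher nearly throughout. Of 34 tested, 33 were higher, with a median of 0.29 and quartiles of 0.20 and 0.39, and 9 rose adjusted over the list alone. TOP2A, the topoisomerase of dividing cells, rose 1.47-fold (1.25 to 1.72). FOXM1, a transcription factor of mitotic genes, rose by 0.57 ± 0.14, the mitotic kinase TTK by 0.47 ± 0.09, the phosphatase CDC25C by 0.45 ± 0.09 and the kinase AURKA by 0.43 ± 0.09. The other probes of CDC25C were at 0.18 and 0.25, and that of FOXM1 at 0.37. CDC20, MCM2, CCNA2 and BIRC5 rose by 0.36 to 0.40, and 25 members did not pass. Over the list alone 16 rose with an offset of 50, and 15 with no background correction or with trend and robust settings. The list had the smallest camera p of all, with adjusted p = 1.6e-10, and adjusted p = 0.388 with an estimated correlation. In fry, which tests the list against no change, the adjusted p was 0.0184. When any 1 array was left out the list still passed in camera, while no single member passed over the list alone, which was also so with no filter, with median scaling and in the authors' series matrix values. The median was 0.053 with median scaling and 0.15 with the authors' averaged-table scaling. Those of interferon-stimulated genes were 0.024 and 0.12, and those of antigen presentation 0.013 and 0.12, with each list still past camera. With median scaling over tested probes the medians of these lists were 0.284, 0.255 and 0.244, and 10 cell-cycle members rose over the list alone.

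Epithelial and mesenchymal markers were lower as a list: of 12 tested, 10 were lower, with a median of -0.20 (adjusted p = 0.0355 in camera, and adjusted p = 0.443 with an estimated correlation). The tight junction protein CLDN1 differed by -0.33 ± 0.12 and the epithelial keratins KRT18 and KRT8 by -0.24 ± 0.10 and -0.21 ± 0.11. Among mesenchymal markers, S100A4, a calcium-binding protein, was 1.27-fold lower (adjusted p = 0.208 in limma). VIM and ACTA2, the 2 higher members, differed by 0.00 ± 0.09 and 0.17 ± 0.11, and TWIST1 and ZEB1 by -0.04 ± 0.34 and -0.10 ± 0.26. The list shift thus does not show that both kinds of marker fell. No member passed, over the list alone or over all genes. Over the list alone 7 fell with median scaling, 7 fell and 1 rose with the authors' averaged-table scaling, and 4 fell with no background correction or with trend and robust settings. With median scaling over tested probes 0 fell. The list's call also ended with cyclic loess (0.0809), both median scalings (0.443 and 0.149), the authors' series matrix values (0.236), their averaged-table scaling (0.0933), no filter (0.482) and probes averaged per gene (0.161), and without control replicate 1 (0.0648), IL-1β replicate 1 (0.0504) or IL-1β replicate 2 (0.18). In fry, which tests the list against no change, the adjusted p was 0.258. Genes of matrix remodelling and adhesion were lower in 11 of 12 members, with a median of -0.15 and adjusted p = 0.0528, and CD44, a hyaluronan receptor, was 1.35-fold lower. That list passed camera with an offset of 50 (adjusted p = 0.0346), no background correction (0.0184), detection on all 4 arrays (0.0492), probes averaged per gene (0.0418) and without control replicate 1 (0.00844), and had adjusted p = 0.443 with an estimated correlation.

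NF-κB regulators and targets moved both ways. Of 29 tested, 16 were higher and 13 lower, with a median of 0.032, and adjusted over the list alone 6 rose and 3 fell. SOD2, the mitochondrial superoxide dismutase, rose 1.53-fold (1.3 to 1.8; its other probes were at 0.70 and 0.22), ZC3H12A by 0.54 ± 0.11, TNFAIP2 by 0.53 ± 0.10, TNIP1 by 0.48 ± 0.09, and NFKB2 and PSMB9 by 0.41 and 0.36. GADD45B, detected on 1 of the 2 IL-1β arrays, fell by 0.80 ± 0.15, CD44 by 0.43 ± 0.10 and NFKB1 by 0.39 ± 0.10. The feedback inhibitors NFKBIA and TNFAIP3 were at 1.15-fold (0.941 to 1.41) and 0.975-fold (0.83 to 1.15). ICAM1 and the receptor IL1R1 were not detected on any array. The list as a whole was not past camera, with adjusted p = 0.539, and its median was -0.03 in the authors' series matrix values, where no member passed over the list alone. With median scaling the median was -0.185, and 0 rose and 2 fell over the list alone. With median scaling over tested probes it was 0.045, and 5 rose and 2 fell. No member passed over the list alone without control replicate 2, IL-1β replicate 1 or IL-1β replicate 2.

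**Figure D3:**
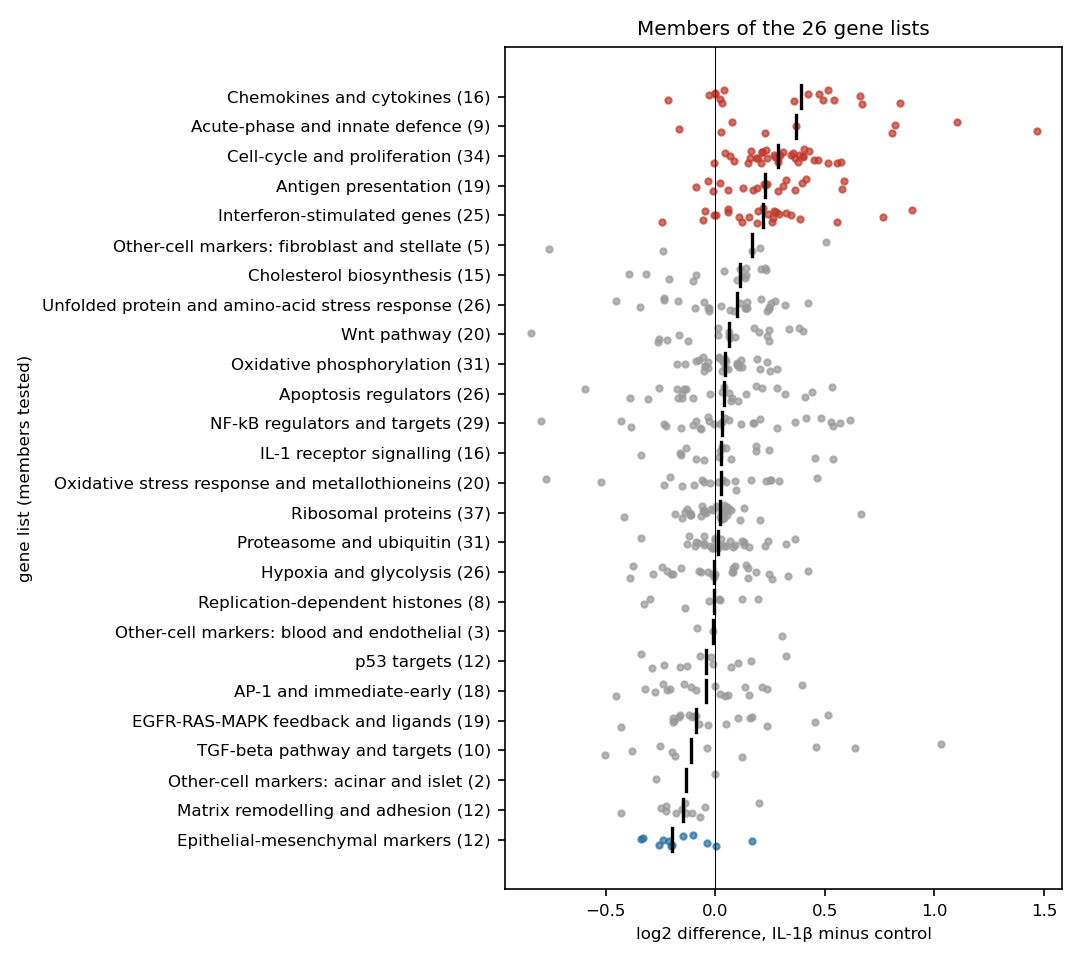
Log2 difference of IL-1β minus control (horizontal axis) for each tested member of the 26 gene lists; points are genes, bars are list medians, and the number tested stands in parentheses. Lists past camera are red (higher) or blue (lower), with medians of 0.39 for chemokines and cytokines, 0.29 for the cell cycle and -0.20 for epithelial and mesenchymal markers. With an estimated correlation none of these lists passed camera (adjusted p = 0.388 or 0.443), in a form with few degrees of freedom here.

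The other lists were not past camera. Of 16 genes of IL-1 receptor signalling, 10 were higher and 6 lower (adjusted p = 0.903), with TAB1 1.45-fold higher and IKBKB at -0.34 ± 0.10. Of 10 TGF-β genes, ID2 and SKI rose and ID3 fell by 0.51 ± 0.14, adjusted over the list alone. ID2 was at least 1.45-fold higher (adjusted p = 0.104 in limma over all probes), since its probe was not detected on either control array, and SKI rose by 0.46 ± 0.11. The median of the TGF-β list was -0.11, while its mean was 0.07 and camera gave the direction up (adjusted p = 0.903). No TGF-β gene passed over the list alone without IL-1β replicate 1, without IL-1β replicate 2 or in the authors' series matrix values, and 1 rose and 0 fell without control replicate 2. Of 19 genes of EGFR, RAS and MAPK feedback, 7 were higher and 12 lower (adjusted p = 0.731). ETV4, a transcription factor downstream of ERK, rose 1.37-fold and HBEGF, an EGFR ligand, fell by 0.43 ± 0.09, both adjusted over the list alone. Neither passed when any 1 array was left out, with no filter or with probes averaged per gene, and 0 rose with median scaling or in the authors' series matrix values. In the Wnt list, 14 of 20 were higher and DKK1 fell adjusted over the list alone (list adjusted p = 0.691).

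In the fit used here, the stress and death lists held no member past the test over the list alone. With median scaling, which moved the tested probes down as a whole, 6 AP-1 genes, 3 p53 targets and 5 apoptosis regulators fell over the list alone. With median scaling over tested probes 0 members of these lists fell. With the authors' averaged-table scaling 5 AP-1 genes and 2 p53 targets fell. With trend and robust settings 5 genes of the unfolded protein response rose and 2 fell, and 5 oxidative stress genes rose and 3 fell. AP-1 and immediate-early genes were 9 higher and 9 lower (adjusted p = 0.691), with ATF3 1.37-fold lower, and p53 targets were 4 higher and 8 lower (adjusted p = 0.691), with AEN 1.26-fold lower. Of 26 apoptosis regulators, 14 were higher (adjusted p = 0.903), with CASP1, the protease that matures IL-1β, 1.36-fold higher. Genes of the unfolded protein and amino-acid stress response were higher in 16 of 26 (adjusted p = 0.389, and 0.0368 in fry, which does not compare the list with other genes). Of 20 oxidative stress genes, 11 were higher and the thioredoxin reductase TXNRD1 was 1.44-fold lower (adjusted p = 0.903), with a median of 0.024 and a mean of -0.01.

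The metabolic and housekeeping lists also held no member past the test over the list alone in this fit. With median scaling 5 hypoxia genes and 2 of cholesterol biosynthesis fell over the list alone, and with the authors' averaged-table scaling 6 and 3 fell. With median scaling over tested probes 0 members of either list fell. Hypoxia and glycolysis genes were 12 higher and 14 lower (adjusted p = 0.903), with ADM 1.3-fold lower. Cholesterol biosynthesis genes were 10 higher and 5 lower (adjusted p = 0.715), with PMVK 1.31-fold lower, and oxidative phosphorylation genes were 21 higher and 10 lower (adjusted p = 0.544), with NDUFB3 1.21-fold higher. Proteasome and ubiquitin genes were 16 higher and 15 lower (adjusted p = 0.715), with the immunoproteasome subunit PSMB9 1.29-fold higher. Replication-dependent histones were 4 higher and 4 lower (adjusted p = 0.731), with H2BC12 1.25-fold lower. Of 37 ribosomal protein genes, 21 were higher and 16 lower, with a median of 0.021, a mean of 0.001 and the camera direction down (adjusted p = 0.903). RPL37 was 1.59-fold higher by 1 probe and differed by -0.07 by the other. The ribosomal list turned up and passed in the authors' series matrix values (adjusted p = 1.69e-05), with the authors' averaged-table scaling (0.00163), with median scaling (0.000181) and with median scaling over tested probes (0.000211).

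Markers of other cell types were mostly below detection. For acinar and islet cells, 2 of 22 genes were tested, CTRC at 1.21-fold lower and CEL at 0.00 on the log2 scale, which were too few for camera. For blood and endothelial cells, 3 of 17 were tested and CD68 was 1.24-fold higher (list adjusted p = 0.734, median -0.01, mean 0.07). For fibroblasts and stellate cells, 5 of 15 were tested, with COL6A3 rising by 0.51 ± 0.11 and COL5A1, detected on 1 of the 2 IL-1β arrays, falling 1.69-fold, adjusted over the list alone (list adjusted p = 0.903, median 0.17, mean -0.02, camera direction up). Neither passed over the list alone without control replicate 1.

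The authors' deposited table of averaged intensities held 1464 probes, of which 228 were higher and 1236 lower after IL-1β, so that 84.4% were lower. The largest folds in the authors' deposited table were 1.89 upward and 2.07 downward, and 66 of its probes were at least 1.5-fold apart. All 1464 were among the probes tested here and had the same direction, 0 passed an adjusted p of 0.05 in limma, and 782 had an unadjusted p under 0.05 (207 higher, 575 lower). In the authors' deposited table of scores, 225 were positive and 1215 negative, and the largest positive score of 340.25 was shared by 19 entries, among them C1S, CCL22 and CFB. Of 1168 of its genes tested here, 97% had the sign of their score. The tables were made from the same 4 arrays and are not independent evidence of a direction.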

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

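The authors' averaged-table scaling, median scaling over tested probes and the counts at an unadjusted p under the alternatives were chosen after seeing the data. All other alternatives were fixed before. The number of arrays limits precision. Where an array was left out the lone array of a group was assumed to vary like the other group. A slide block was not run, since the column names give no slide. Except where a cause is given, the cause was not tested. Main values were 0 probes past an adjusted p of 0.05, 401 by the size rule and 6 lists. With the replicate block, 0 probes passed the adjusted p, 2028 had an unadjusted p under 0.05 (2437 without it), 401 met the size rule, and no list call changed; cell-cycle members past the list-alone adjustment numbered 0 (9 without it), EGFR and MAPK members 0 (1 higher and 1 lower without it), TGF-β members 1 higher and 0 lower (2 and 1), and NF-κB members 4 and 1 (6 and 3). The labels do not say that a number marks a pair, and deviations of same-numbered arrays correlated at -0.0868 across probes.

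Probes past the adjusted p numbered 254 with normexp at offset 50, 624 with no background correction, 919 with median scaling (58 higher, 861 lower), 10 with median scaling over tested probes, 1097 with the authors' averaged-table scaling (239 higher, 858 lower), 66 when detected on all 4 arrays, 728 with trend and robust settings and 124 at an adjusted p of 0.1. The count was 0 with cyclic loess, the series matrix values, no filter, averaged probes and with any 1 array left out. By the size rule, 91 probes were counted with offset 50, 47 with no background correction and 66 with the averaged-table scaling, where a larger background added to each value shrinks folds by construction; 873 met it with median scaling, 682 in the series matrix values, 875 with no filter, 222 when detected on all 4 arrays and 32 at 2-fold. With 1 array left out, non-overlap with a lone array is easier to meet, so those counts do not compare with the main one. All tested named genes kept their direction in every setting except CXCL8 and CXCL1.

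With the correlation estimated, 0 lists passed, at medians of 0.39 (chemokines), 0.369 (acute phase), 0.219 (interferon), 0.285 (cell cycle), 0.228 (antigen presentation) and -0.2 (epithelial and mesenchymal markers). With fry, which tests a list against no change and not against other genes, the interferon (0.219), antigen presentation (0.228) and epithelial and mesenchymal (-0.2) lists did not pass. The cell-cycle, acute-phase and chemokine lists passed fry. The epithelial and mesenchymal list also did not pass with median scaling (-0.397), median scaling over tested probes (-0.166), cyclic loess (-0.192), the series matrix values (-0.268), the averaged-table scaling (-0.258), no filter (-0.081) or averaged probes (-0.141), and its median was -0.264 to -0.131 with 1 array left out. The other called lists passed each time 1 array was left out.

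The camera direction turned in lists that had not passed in the main setting, at these medians. Ribosomal proteins, which turned up and passed under both median scalings, the series matrix and the averaged-table scaling: median scaling -0.032, median scaling over tested probes 0.199, cyclic loess 0.081, series matrix 0.125, averaged-table scaling 0.066, averaged probes 0.01, and -0.034 to 0.015 with 1 array left out. Hypoxia: -0.158, 0.073 and -0.002 with both median scalings and the series matrix. TGF-β: no filter -0.037, detected on all 4 arrays -0.11, averaged probes -0.189. Apoptosis: averaged-table scaling -0.075, averaged probes 0.002. IL-1 receptor: detected on all 4 arrays 0.017. Cholesterol and proteasome: averaged-table scaling 0.003 and -0.078. With 1 array left out it also turned in IL-1 receptor signalling (-0.088 to 0.072), TGF-β (-0.138 to 0.07), apoptosis (0.018 to 0.052), hypoxia (-0.006 to 0.003), oxidative stress (0.003 to 0.024), histones (-0.133 to 0.071) and fibroblast markers (0.07 to 0.144).

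Among genes near no difference, the sign turned for CXCL8 with median scaling over tested probes (0.114), cyclic loess (0.01), the series matrix (0.04) and averaged probes (0.005), for C3 with the averaged-table scaling (0.003), and for CXCL5 with median scaling (-0.199), the series matrix (-0.045), the averaged-table scaling (-0.08) and averaged probes (-0.004). With 1 array left out it turned for CXCL8 (-0.012 to 0.005), CXCL1 (-0.087 to 0.087), C3 (-0.462 to 0.131) and CXCL2 (-0.067 to 0.008).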

Other observations

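Of the tests below, those of the authors' mean scaling, of the brightest 1% of probes and of the scanner ceiling were chosen after the result was seen, as were the genes named here. These single genes lie outside the lists; none passed the adjusted p in the default limma fit, and no group was tested for them. GDF15, a stress-induced cytokine of the TGF-β family, differed by 0.88 on the log2 scale, and NUPR1, a transcriptional regulator first described in the pancreas, by 0.96 and 0.86 at its probes. The replication factors MCM10 (0.87 and 0.61) and LIG1 (0.85), the hyaluronan receptor HMMR (0.68 and 0.78) and CHI3L2, a chitinase-like secreted protein (0.95), were also higher. FHL2, a LIM-domain cofactor of transcription, was at -0.81 and -0.69, and NOG, a secreted antagonist of BMP signalling, at -0.82.

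RAB27B, a small GTPase of secretory vesicles, was at -0.77 and at -0.25 by its brightest probe, SYTL2, which binds RAB27 proteins, was at -0.89 and -0.23, and MYO5A, a motor protein for vesicles, was at -0.90. A further, dim probe of RAB27B was at -1.28, a size that is uncertain since it was not detected on the IL-1β arrays. The differences vary between probes of the same gene, so their extent is unclear.

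Most probes of the authors' deposited tables were lower after IL-1β. With the authors' averaged-table scaling, 72% of probes with an unadjusted p under 0.05 were lower, while the 50.1% with neqc follows from its centring. The probes of the averaged table itself were 84.4% lower both with neqc and with the authors' scaling, at medians of -0.203 and -0.274. They kept their direction in neqc, so the scaling by mean intensity may be a part of the excess only through which probes were listed. For the brightness of the probes, 52% of 934 such probes brighter than the median were lower with neqc, but quantile normalization removes such a shift, so this excludes nothing, and with the authors' scaling the median ran from 0.057 in the dimmest of 10 brightness classes to -0.11 in a brighter one. Leaving the brightest 1% of probes out of the scaling moved the median by 36.4% toward 0, which explains less than the whole. A general lowering of RNA stays open, since quantile normalization centres the arrays and no spiked-in RNA was used here.

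The cell-cycle list was higher after IL-1β in camera with the preset correlation and in fry (adjusted p = 0.0184). With an estimated correlation, where camera has few degrees of freedom, the list had adjusted p = 0.388. Its median was 0.053 with median scaling, which moved the tested probes down as a whole, and 0.284 with median scaling over tested probes. Its median of 0.285 lay at percentile 100 of 10000 random lists matched for brightness, whose highest median was 0.156. Brightness alone thus does not give such a median in these values. Quantile normalization left each brightness class near 0 (-0.014 to 0.009), so this outcome was largely set beforehand and excludes no other residue of normalization. Random lists also do not carry the correlation of these genes. Within groups its median differed between arrays by at most 0.01, but that spread may be technical, since the labels do not state separate cultures, so variation in growth between cultures cannot be told apart from a response. A difference in cell density or growth between the groups at harvest, caused by IL-1β or not, could give the same values and was not tested.

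CXCL1, CXCL2, CXCL5 and CXCL8 were under 1.1-fold apart in the fit used here, though CXCL1 and CXCL2 were at -0.25 and CXCL5 at -0.20 with median scaling, while complement genes and other chemokines were higher. Probes at least as bright as CXCL1 were 1.5-fold apart in 0.9% of cases against 4.46% of dimmer probes. Their spread within groups was also smaller (0.0738 against 0.139), so these shares cannot tell compression of bright signals from lower noise. CXCL1, CXCL2 and CXCL5 had mean log2 intensities of 9.088, 10.657 and 10.406. The brighter IFI27, LCN2 and SOD2 (11.667, 12.3 and 12.46) rose by 0.898, 0.822 and 0.615. These rises argue against compression as the reason for the values of CXCL1, CXCL2 and CXCL5, but do not reach the brightness of CXCL8 (13.654). Among the 200 probes at least as bright as CXCL8, the SD of differences was 0.106 against 0.249 for all, but their spread within groups was also smaller (0.0711 against 0.106). CXCL8 lay at 44.3% of its array's maximum, and CD44, brighter still, differed by -0.43, so whether saturation hides a difference at CXCL8 stays open. CXCL1, CXCL2 and CXCL5 reached at most 6.08% of the array maximum, so a scanner ceiling does not account for their values, while an early response that had ended by 36 h could give them and was not tested.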
